A study of Homo sapiens with 24 samples.

How the data were processed

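RNA was measured in 24 libraries of WI-38 cells, 3 for each of a control siRNA and 7 siRNA targets. Per the labels' protocols, RNA was purified with RNeasy and libraries were made with a stranded total RNA kit after siRNA transfection and harvest at 72 h. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20.0.422, aligned to hg38 with STAR 2.7.0f and counted per gene with featureCounts of Subread, whose version is given as 2.10.5. The deposited values are raw counts per gene. The notes state neither the strand setting nor how reads with several alignments were counted. Near-identical gene copies held almost the same counts (ratios 0.996 to 1), so reads shared by copies appeared to be counted at each.

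The table held 60605 genes, of which 60463 matched a name table and 58337 matched GENCODE release 29, used for biotypes and coordinates. Total counts per library ranged from 70260779 (COPE replicate 3) to 92621203 (COPB2 replicate 1). Counts on 7SL and 7SK genes made up 9.18 to 21.81%, on rRNA genes 0.07 to 14.13%, on mitochondrial genes 0.13 to 1.37% and on protein-coding genes 62.71 to 87.34%. No 2 libraries of a group had identical counts. Checked as repeats of 1 library, pairs within a group differed by a chi-squared per degree of freedom of 9.8 to 261.

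Genes with low counts were removed with filterByExpr by group, which kept 21409 genes and left out 39196. Library sizes were scaled by TMM. All 24 libraries were fitted with edgeR 4.0.16 by group with the quasi-likelihood test in R 4.3.3 (common biological coefficient of variation 0.169, median prior degrees of freedom 5.92). Each knockdown was compared with control siRNA and with the mean of the other 6 knockdowns, and the 7 knockdowns were tested jointly for any difference. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. CPM are TMM-scaled means with SD over 3 libraries, and log2 fold changes carry the SE of the fit. Counts per targeted gene and library were made into CPM in the same way.

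Gene lists (19 lists, 584 members) were written before the data were examined and tested with camera of limma 3.58.1 with an inter-gene correlation preset to 0.01, adjusted over the 133 tests of a family (7 knockdowns by 19 lists). Lists needed 5 tested members. An estimated correlation and the rotation test fry served as alternatives. Lists covered the coat, vesicle traffic, endoplasmic reticulum chaperones, the integrated stress response, Golgi glycosyltransferases, autophagy and lysosome, lipid droplets, cholesterol synthesis, oxidative phosphorylation, cell cycle, p53 targets, the secretory phenotype, NF-kB, interferon response, matrix, contractile genes and markers of epithelial, endothelial and leukocyte cells. Genes were named by a rule set at the same time: the coat genes, 11 fixed genes (CDKN1A, CDKN2A, CDKN2B, LMNB1, HMGB1, IL6, CXCL8, HSPA5, DDIT3, COL1A1 and MKI67), and called genes with the largest change. These were 6 rises and 6 falls against control, 3 and 3 against the other knockdowns, and 8 and 8 shared by all 7, with a mean log2 CPM of at least 1 and no overlap between the libraries compared. From each called list the rule took the 2 members with the largest change in the direction of the list, and the text gives some of them. A gene that the rule named is not reported here.

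Fold changes were correlated between knockdowns over 21409 genes. Groups without a change were simulated 20 times together with a control group that they share. All 24 libraries, the 3 controls included, were drawn from the mean of the real controls. This gave the correlation that a shared control group alone produces in such counts. On simulated counts with 200 changed genes per knockdown (20739 genes in the fit), edgeR recovered 41.8 to 63.6% of 1.5-fold, 82.1 to 92.5% of 2-fold and 97 to 100% of 4-fold changes over the 7 knockdowns, with 2 to 11 false calls. A list shifted by 0.5 in COPG1 was called (adjusted p = 9.84e-37) with 0 of 132 other list tests. Genes were drawn independently in these counts, so the simulation does not show how often correlated members of a list would give false list calls. Principal components used the 2000 most variable genes.

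Alternatives set before the libraries were seen were DESeq2 1.42.0 (size factors alone and its own test), no and stricter low-count filters, the replicate number as a block, fits of 1 knockdown with control, an absolute log2 fold change of at least 1, and leaving out each library in turn. Another 5 alternatives were added after the data had been seen: 2 covariates, GC and length offsets in 20 by 5 bins, protein-coding genes alone, and leaving out the library of each knockdown with the highest mitochondrial rRNA level. The mitochondrial rRNA level was tried first as a covariate and the RPS16 level second. The RPS16 level is the log2 CPM of RPS16 minus the mean of 72 other ribosomal protein genes.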

Results

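The series measured gene expression in WI-38 cells, a line of diploid human fetal lung fibroblasts with a finite replicative lifespan, after siRNA against single subunits of coatomer. Coatomer, or COPI, is the protein coat of vesicles that carry cargo from the Golgi back to the endoplasmic reticulum and between Golgi cisternae. The title places these subunits in the context of cell senescence. The 24 libraries fall into 8 groups of 3, a control siRNA group and 7 knockdown groups named by their target: COPA, COPB1, COPB2, COPD, COPE, COPG1 and COPZ1. COPD is the older name of ARCN1, which encodes the delta subunit. Cells were harvested at 72 h. Total counts per library ranged from 70260779 to 92621203, and counts on protein-coding genes from 46265706 to 76489804. All fold changes are log2 values ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3 libraries per group. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

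The targeted mRNA was low in each of the 21 knockdown libraries. COPA mRNA stood at 40.5, 31.5 and 39.9 CPM in the COPA knockdown and at 304, 315.4 and 320.2 CPM in the controls, which left 11.9% of the control mean. COPB1 mRNA stood at 27.1, 26.6 and 23.5 CPM in its knockdown, 4.2% of control, and COPB2 mRNA at 38.7, 43.2 and 39.9 CPM, 7.5% of control. ARCN1 mRNA in the COPD knockdown was 16.8, 16.9 and 16.9 CPM, 6.97% of control. COPE mRNA was 4.8, 4.8 and 4.9 CPM in its knockdown, or 4.66% of control. COPG1 mRNA was 51, 47.1 and 45.9 CPM in its knockdown, 14.7% of control, and COPZ1 mRNA was 10.6, 8.6 and 9.1 CPM, 4.68% of control. The fitted changes ran from -2.77 ± 0.07 for COPG1 (adjusted p = 9.48e-18) to -4.57 ± 0.21 for COPB1 (adjusted p = 1.48e-13). No library went against its label. On the GRCh38 annotation COPA lies on chromosome 1 (160288686 to 160343400) and COPB1 on chromosome 11 (14443440 to 14500027). COPB2 lies on chromosome 3 (139355600 to 139389732) and ARCN1 on chromosome 11 (118572390 to 118603033). COPE lies on chromosome 19 (18899514 to 18919397), COPG1 on chromosome 3 (129249606 to 129277773) and COPZ1 on chromosome 12 (54301202 to 54351849).

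**Figure D1:**
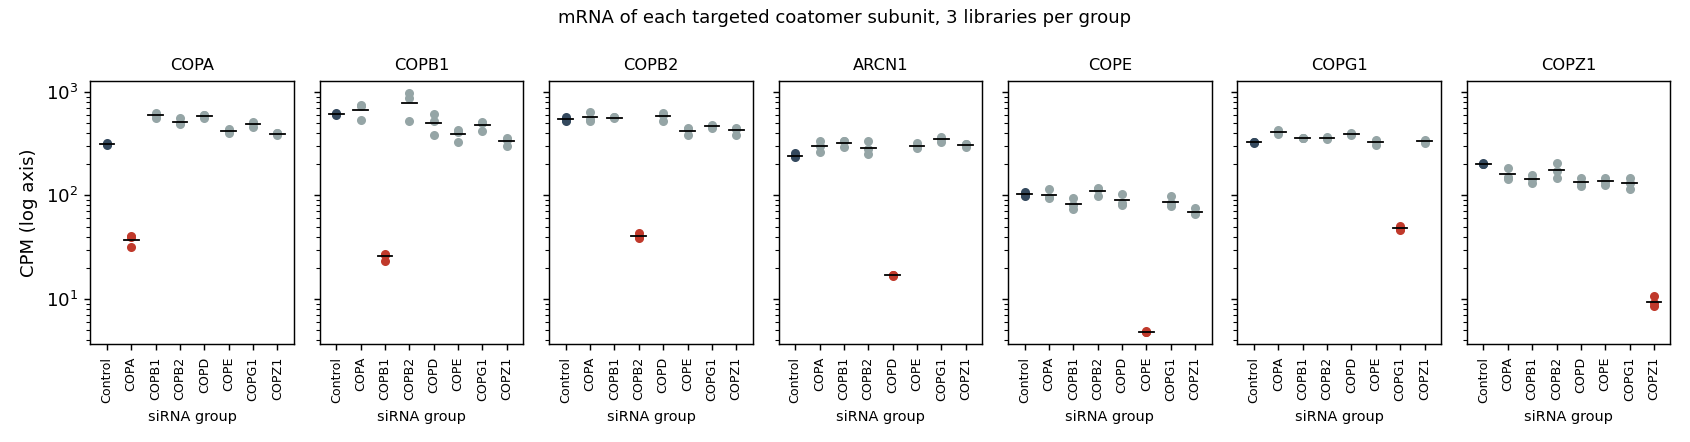
CPM (log axis) of each targeted coatomer mRNA in the 24 libraries; points are libraries, red in the group targeted, dark in control, and short lines are means of 3. The 3 targeted libraries of each panel lie below all 21 others, with group means between 4.2% and 14.7% of the control mean.

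Some subunits that were not targeted changed as well, by less than the targeted one. COPA mRNA rose by 0.93 ± 0.09 in the COPB1, 0.72 ± 0.09 in the COPB2, 0.91 ± 0.09 in the COPD and 0.64 ± 0.09 in the COPG1 knockdown (highest adjusted p = 2.52e-06). It was also called in COPE (0.42 ± 0.09) and COPZ1 (0.33 ± 0.09), calls that ended with GC and length offsets (0.08 and -0.01) and with the RPS16 level described next (0.1 and 0.01). ARCN1 was called higher in the 6 knockdowns that did not target it, from 0.25 ± 0.1 in COPB2 to 0.52 ± 0.1 in COPG1, and only the COPG1 call held with the RPS16 level (0.28). Without 1 library the ARCN1 call was lost in COPB2 in 4 cases (0.13, adjusted p = 0.278, without COPB2 replicate 3), in COPA in 1 (0.0933) and in COPE in 2 (0.0676 and 0.0539). COPZ2, the paralog of COPZ1, rose by 0.59 ± 0.09 in the COPB2, 0.65 ± 0.09 in the COPD and 0.63 ± 0.09 in the COPG1 knockdown. It was also called higher in COPA (0.3 ± 0.09) and COPB1 (0.22 ± 0.09), calls that ended with GC and length offsets (0.2 and 0.21). In the COPZ1 knockdown it was not called (0.12 ± 0.09). COPG1 mRNA was called higher in COPA (0.34 ± 0.07) and COPD (0.26 ± 0.07), the COPD call ending with GC and length offsets (0.16). COPG2, the paralog of COPG1, fell by 1 ± 0.22 in the COPB2 knockdown (adjusted p = 0.000826). It was called higher in COPE (0.57 ± 0.22), COPG1 (0.64 ± 0.22) and COPZ1 (0.57 ± 0.22), calls that ended with the RPS16 level (-0.29, -0.02 and -0.28) and also when single libraries were left out (adjusted p = 0.142 in COPG1 without COPG1 replicate 3). COPZ1 mRNA was lower in the COPA (-0.33 ± 0.12), COPB1 (-0.49 ± 0.12), COPD (-0.58 ± 0.12), COPE (-0.56 ± 0.12) and COPG1 (-0.62 ± 0.12) knockdowns, and none of these passed the threshold once the RPS16 level entered the model (-0.06, -0.14, -0.23, -0.06 and -0.25). The same held for COPE mRNA in the COPZ1 knockdown (-0.57 ± 0.11, then -0.12) and for COPB1 mRNA in the COPE (-0.65 ± 0.19, then 0) and COPZ1 knockdowns (-0.88 ± 0.19, then -0.23). The list of 9 coat genes as a whole was called in no knockdown against control (lowest adjusted p = 0.35, in COPE). Between 3 and 4 members were higher and 2 to 4 lower. Its median was above 0 in 6 knockdowns and its mean below 0 in all 7 (0.08 and -0.25 in COPA), and the targeted gene is part of the list.

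The libraries also differed in a property that ran across the groups. RPS16, a gene of the small ribosomal subunit, lay far below the mean of 72 other ribosomal protein genes in the controls (log2 difference -7.15 ± 0.48, SD, n = 3). It was closest to them in the COPE (-1.37 ± 0.43) and COPZ1 (-1.48 ± 0.6) groups. Within the COPA group it ranged from -6.59 to -1.78 and within the COPB1 group from -5.36 to -0.81. With the group means held, 7455 of 21409 genes followed this level across libraries, against 0 in each of 40 shuffles of the level within groups. HSPA5, COL1A1 and MYL9 are among the named genes whose values depended on it. RPS16 has processed copies in the genome, and how reads shared with them were counted is not stated. The share of counts on 7SL and 7SK RNA genes was lowest in the same 2 groups, at 9.97% ± 0.99 in COPE and 12.19% ± 0.95 in COPZ1 against 17.66% ± 1.21 in control (SD, n = 3). Because the level differs between groups, values from a fit that also holds it as a covariate are given below for list calls that they end or start and for many of the named genes, and the covariate was chosen after the data had been seen. That fit assumes for each gene the same straight slope on the level in all groups. Control libraries did not overlap those of COPE or COPZ1 in the level, so the adjusted values there depend on this assumption.

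**Figure D2:**
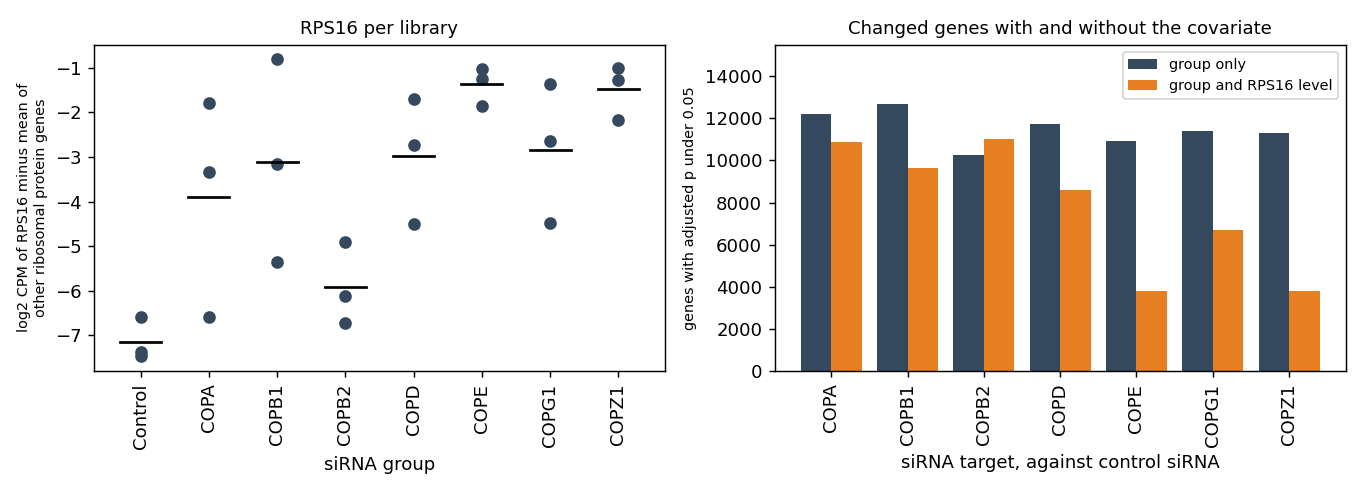
Left, log2 CPM of RPS16 minus the mean of 72 other ribosomal protein genes, where points are libraries and lines are means of 3. Right, genes with adjusted p under 0.05 against control, without the RPS16 level in the model and with it; the count falls from 10929 to 3811 in COPE and from 11308 to 3809 in COPZ1.

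The first question was what each knockdown changed against control siRNA. In COPA knockdown cells the stress response and NF-kB target lists were higher and the contractile and cell cycle lists lower, with values given below. INHBE, which encodes an inhibin beta subunit, rose from 0.24 ± 0.10 to 66.9 ± 0.17 CPM (SD, n = 3), a change of 8.1 ± 0.17 (adjusted p = 2.32e-19). BEX2 rose by 8.12 ± 0.37, ARFGEF3 by 7.94 ± 0.39, the small GTPase gene RAB39B by 7.29 ± 0.32 and the metalloproteinase gene PAPPA2 by 7.25 ± 0.26, each from at most 0.103 CPM in control. RPLP0P2, a ribosomal protein pseudogene whose reads can be shared with its parent gene, rose by 8.72 ± 0.28. The largest falls were in WNT2 (-6.21 ± 0.29), the matricellular gene CCN4 (-5.38 ± 0.16), RASL11A (-5.34 ± 0.17), the interferon-inducible GTPase gene GBP1 (-4.85 ± 0.16), MEST (-4.76 ± 0.16) and the protocadherin gene PCDH18 (-4.75 ± 0.14). In all, 12195 of 21409 genes tested changed, 6174 higher and 6021 lower.

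COPB1 knockdown changed 12673 genes, 6504 higher and 6169 lower. INHBE (8.24 ± 0.18), ARFGEF3 (7.95 ± 0.39), BEX2 (7.5 ± 0.37) and RAB39B (7.49 ± 0.32) again led the rises. RASL11A (-5.6 ± 0.17), the interferon-induced gene IFIT1 (-4.54 ± 0.34), CCN4 (-4.33 ± 0.14), PDGFD (-4.28 ± 0.24), a growth factor gene of the PDGF family, and the glutamate receptor gene GRIA4 (-3.96 ± 0.21) fell most beside the target. The 5.8S rRNA copies RNA5-8SN2 and RNA5-8SN3 also ranked among the rises (7.56 ± 2.74 and 7.26 ± 2.67), but their adjusted p was 0.16 and 0.174 without COPB1 replicate 3, and the RPS16 level ended both calls (1.74 and 1.49). Near-identical rRNA copies appeared to hold the same reads.

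COPB2 knockdown changed 10262 genes, 5187 higher and 5075 lower. INHBE rose by 7.84 ± 0.17, RPLP0P2 by 7.05 ± 0.28, ARFGEF3 by 6.7 ± 0.39, PAPPA2 by 6.29 ± 0.25 and BEX2 by 6.05 ± 0.38. PDE7B-AS1, an antisense transcript that cannot be told from its partner where strand use in counting is not stated, rose by 6.36 ± 0.28. RASL11A (-5.33 ± 0.17), WNT2 (-4.47 ± 0.25), the protease gene ADAMTS15 (-4.12 ± 0.24), GRIA4 (-4.09 ± 0.21), the mitotic kinase gene CDK1 (-4.09 ± 0.19) and CCN4 (-4.02 ± 0.14) fell most.

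COPD knockdown changed 11710 genes, 6081 higher and 5629 lower. INHBE (7.36 ± 0.17), RPLP0P2 (7.07 ± 0.28), ARFGEF3 (6.77 ± 0.39) and RAB39B (6.77 ± 0.32) were among the largest rises. RASL11A (-4.56 ± 0.16), GRIA4 (-4.27 ± 0.21), the growth factor gene BMP4 (-4.05 ± 0.12), the interferon-inducible GTPase gene GBP2 (-4 ± 0.15) and CCN4 (-3.88 ± 0.14) fell most. RNA5-8SN2 stood at 7 ± 2.69 and lost its call without COPD replicate 1 (1.57, adjusted p = 0.645) and with the RPS16 level (0.84).

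In the COPE knockdown SERPINB2, a plasminogen activator inhibitor gene, rose from 1.09 ± 0.33 to 32.4 ± 2.16 CPM (4.88 ± 0.16, adjusted p = 1.26e-15) and kept that change with the RPS16 level in the model (4.74). RPS16 itself (5.4 ± 1.21), the myosin light chain gene MYL9 (3.78 ± 0.78), COL1A1 (3.67 ± 0.63), MT-ATP8 (3.89 ± 1.5) and MTATP6P1 (3.59 ± 1.26) completed the largest rises. The level is built from RPS16, so the loss of the RPS16 call with it (0.13) was fixed in advance. The other genes of these lost their calls with that level (0.36, 1.23, 0.32 and 0.14). MT-ATP8 and its nuclear-copy neighbour MTATP6P1 also lost them without COPE replicate 3 (adjusted p = 0.349 and 0.203). RIDA, an imine deaminase gene (-3.55 ± 0.22), IFIT1 (-3.01 ± 0.31), GRIA4 (-2.94 ± 0.19), MEDAG (-2.91 ± 0.16) and the gliomedin gene GLDN (-2.88 ± 0.22) fell most beside the target. Of 10929 genes called, 5619 were higher and 5310 lower, and 3172 of them were also called in the same direction with the RPS16 level in the model, which called 3811.

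COPG1 knockdown raised ADM2, which encodes a peptide hormone (5.56 ± 0.45), and the glycine transporter gene SLC6A9 (5.11 ± 0.47). It lowered KYNU, an enzyme of tryptophan breakdown (-3.67 ± 0.2), IFIT1 (-3.52 ± 0.32), the cell cycle gene CKS1B (-3.51 ± 0.13), SLC35F3 (-3.39 ± 0.19) and the DNA replication gene GINS2 (-2.8 ± 0.23). RNA5-8SN1, RNA5-8SN2 and RNA5-8SN3 stood at 7.91 to 8.24, and each lost its call without COPG1 replicate 3 (adjusted p = 0.22, 0.179 and 0.197) and with the RPS16 level (1.34, 1.97 and 1.73). Of 11404 genes called, 5855 were higher and 5549 lower, and 6677 genes were called with the RPS16 level in the model.

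COPZ1 knockdown raised RPLP0P2 (4.88 ± 0.29) and lowered IFIT1 (-2.95 ± 0.31), the apoptosis inhibitor and mitotic gene BIRC5 (-2.89 ± 0.13), GRIA4 (-2.88 ± 0.19), RASL11A (-2.67 ± 0.14) and the histone gene H3C7 (-2.55 ± 0.19). RPS16 rose by 5.38 ± 1.21, and the loss of its call with the RPS16 level (0.16) was fixed in advance, because it defines that level. RNA5-8SN1 (7.36 ± 2.7), RNA5-8SN2 (7.71 ± 2.76) and RNA5-8SN3 (7.41 ± 2.68) lost their calls with the RPS16 level (0.19, 0.86 and 0.63). The 5.8S copies lost them without COPZ1 replicate 2 as well (adjusted p = 0.0777, 0.0677 and 0.0727). Of 11308 genes called, 5768 were higher and 5540 lower, and 3254 were also called in the same direction with the RPS16 level, which called 3809.

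Gene groups fixed before the data were examined were then compared with all other genes by limma's camera test over 133 list tests. The integrated stress response is the ATF4 and CHOP program that raises amino acid synthesis and transport. As a list its 36 genes were higher in all 7 knockdowns, with median log2 changes of 2.48 in COPA, 2.53 in COPB1, 1.85 in COPB2, 1.99 in COPD, 0.66 in COPE, 2.12 in COPG1 and 1.12 in COPZ1 (highest adjusted p = 0.000126, in COPE). In that order 36, 35, 36, 33, 23, 32 and 28 members rose, and 8 fell in COPE, 3 in COPG1 and 2 in COPZ1. Adjusted over the list alone, 29 rose in COPZ1 and 3 fell, and the other counts were the same. PSAT1, an enzyme of serine synthesis, rose by 2.74 ± 0.3 in COPE and by 4.78 ± 0.33 in COPG1. DDIT3, which encodes CHOP, rose by 3.7 ± 0.18 in COPA, 3.3 ± 0.18 in COPB1, 2.93 ± 0.18 in COPB2, 3.05 ± 0.18 in COPD, 1.06 ± 0.17 in COPG1 and 0.87 ± 0.17 in COPZ1. In COPE it was lower (-0.48 ± 0.17, adjusted p = 0.02), a call lost without COPE replicate 3 (adjusted p = 0.121) and at 0.17 with the RPS16 level. FGF21 had no counts in the 3 control libraries and reached 0.19 ± 0.09 CPM in COPA.

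Chaperones and folding enzymes of the endoplasmic reticulum rose as a list of 35 in 4 knockdowns, with medians of 0.9 in COPA and COPB1, 0.27 in COPB2 and 0.75 in COPD (highest adjusted p = 0.0164, in COPB2, and 0.0568 there with an estimated correlation). Members higher numbered 25, 25, 17 and 24, and lower 4, 5, 8 and 4. The counts adjusted over the list alone were 25, 25, 17 and 27 higher and 4, 7, 8 and 4 lower. HSPA5, the chaperone BiP, rose by 4.08 ± 0.5 in COPA, 4.68 ± 0.52 in COPB1, 2.27 ± 0.47 in COPB2 and 4.09 ± 0.5 in COPD. It was also called higher in COPE (2.1 ± 0.46), COPG1 (2.11 ± 0.46) and COPZ1 (2.72 ± 0.47), where the RPS16 level ended the call (0.15, 0.59 and 0.81; adjusted p = 0.828, 0.124 and 0.0969). The list was not called in COPE (median -0.19, 12 higher and 14 lower), COPG1 (-0.04, 16 and 10) or COPZ1 (0.05, 13 and 10), and with the RPS16 level it was called higher in COPG1 (0.27, adjusted p = 0.0206) and COPZ1 (0.08, 0.0463). Its median was below 0 and its mean above in COPE (mean 0.1) and COPG1 (mean 0.41). Genes of vesicle traffic between endoplasmic reticulum and Golgi, a list of 48, rose in COPA (median 0.6, 29 higher and 2 lower), COPB1 (0.53, 32 and 4), COPB2 (0.44, 27 and 5), COPD (0.61, 29 and 4) and COPG1 (0.31, 26 and 9), with a highest adjusted p of 0.00807. The counts adjusted over the list alone were the same in these 5 knockdowns. ARF4, a small GTPase of this pathway, rose by 2.74 ± 0.11 in COPA and SEC31A, a COPII coat gene, by 1.81 ± 0.08 in COPB2. SEC16A and TMED9 (1.77 ± 0.41 and 1.61 ± 0.35 in COPG1) lost their calls with the RPS16 level (0.35 and 0.43). The list was not called in COPE (median 0, 17 higher and 11 lower) or COPZ1 (0.13, 22 and 13), and with the RPS16 level it was called in COPZ1 (0.1, adjusted p = 0.0183).

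Cell cycle genes fell in 6 knockdowns. The medians of the 49 genes were -1.49 in COPA, -1.4 in COPB1, -2.01 in COPB2, -1.63 in COPD, -1.37 in COPG1 and -1.25 in COPZ1 (highest adjusted p = 1.52e-14), with 44, 41, 45, 40, 41 and 40 members lower. With p adjusted over the list alone these were 44, 41, 46, 40, 41 and 40. CDK1 fell by 3.43 ± 0.18 on the log2 scale in COPA, by 2.75 ± 0.17 in COPB1, by 3.2 ± 0.18 in COPD and by 2.25 ± 0.17 in COPZ1, KIF20A by 3.63 ± 0.13 in COPB2 and HMMR by 2.69 ± 0.19 in COPG1. In COPE 21 members rose and 6 fell, the same adjusted over the list alone. The list was not called there (median 0.23, adjusted p = 0.0661), and it was called without COPE replicate 3 (0.34, adjusted p = 0.0216) and without Control replicate 1 (0.26, adjusted p = 0.0413). It was also called with GC and length offsets (0.28, adjusted p = 0.022) and with the RPS16 level (0.46, adjusted p = 0.000114). MKI67, the proliferation marker Ki-67, rose in COPE (1.8 ± 0.25) and fell in COPA (-0.96 ± 0.26) and COPB2 (-2.22 ± 0.27), and it was not called in the other 4 (-0.38 in COPB1 to 0.16 in COPZ1). In the model with the RPS16 level MKI67 was called lower in those 4 as well (-1.18 in COPB1, -1.06 in COPD, -0.92 in COPG1 and -0.9 in COPZ1, highest adjusted p = 0.00815). LMNB1, the lamin gene whose loss is a marker of senescence, rose in COPE (0.89 ± 0.14) and fell in the other 6, from -0.71 ± 0.14 in COPZ1 to -2.26 ± 0.15 in COPA, and the RPS16 level ended the COPZ1 call (-0.3). The CDK inhibitor gene CDKN2B rose in all 7, from 0.96 ± 0.08 in COPD to 1.65 ± 0.09 in COPG1. CDKN2A rose in COPE (0.67 ± 0.1), COPG1 (0.58 ± 0.1) and COPZ1 (0.82 ± 0.1), and its values in the other 4 lay between 0.15 and 0.19. CDKN1A was -0.45 ± 0.08 in COPB1, -0.53 ± 0.08 in COPB2, -0.36 ± 0.08 in COPD and -0.44 ± 0.08 in COPE, the last losing its call with the RPS16 level (-0.26). It was not called in COPA (-0.15), COPG1 (-0.12) or COPZ1 (0.11). With GC and length offsets it was called lower in COPA (-0.31, adjusted p = 0.00409) and COPG1 (-0.39, 0.000587), and with the RPS16 level it was called higher in COPZ1 (0.29, 0.0452). HMGB1 fell in all 7, from -0.61 ± 0.14 in COPE, where the RPS16 level ended the call (-0.06), to -1.66 ± 0.14 in COPB1. The 30 targets of p53 were not called in any knockdown, with medians from -0.08 in COPE to 0.19 in COPA, 7 to 13 members higher and 9 to 13 lower. They were called higher in COPZ1 with the RPS16 level (0.18, adjusted p = 0.0466).

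**Figure D3:**
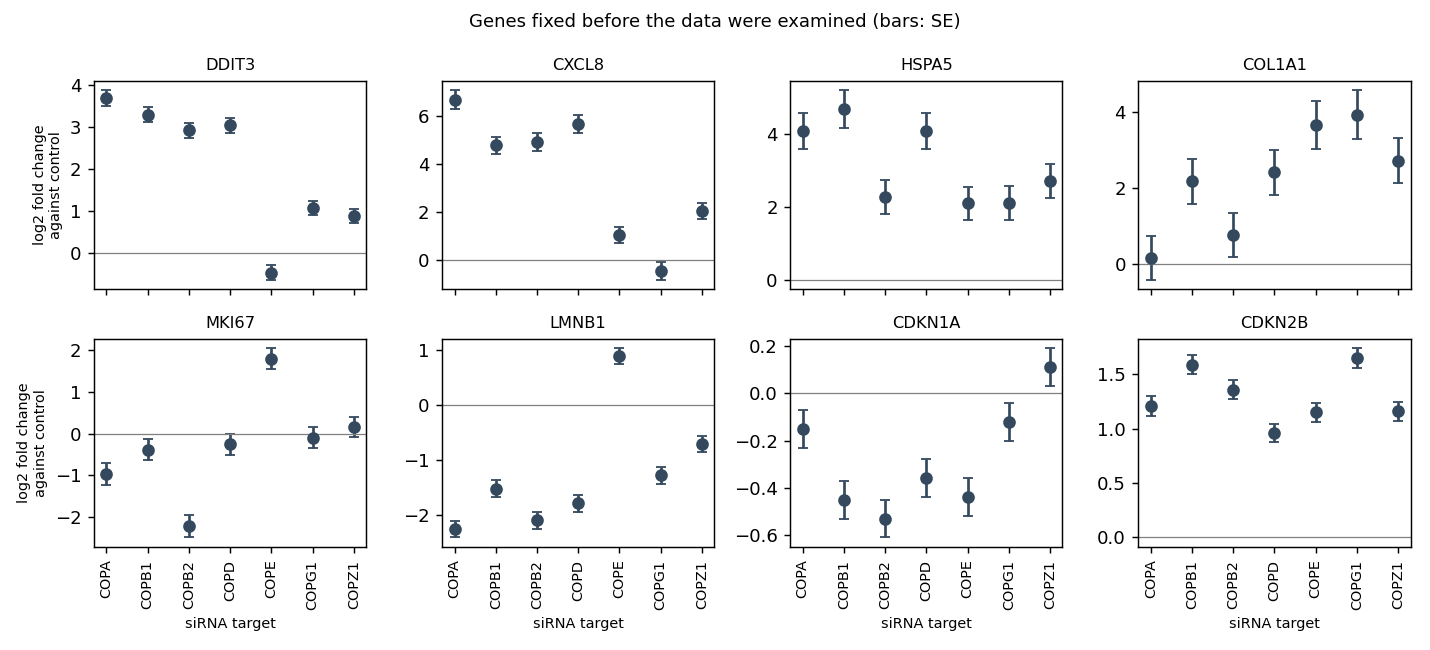
Log2 fold change against control siRNA of 8 genes fixed before the data were examined, in each of the 7 knockdowns; points are fitted values and bars are SE from 3 libraries per group. DDIT3 ranges from 3.7 in COPA to -0.48 in COPE, and MKI67 is at 1.8 in COPE and -2.22 in COPB2.

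Inflammatory genes rose unevenly. The 22 targets of NF-kB were called higher in COPA (median 0.75), COPB1 (0.83), COPB2 (0.36), COPD (0.71), COPG1 (0.44) and COPZ1 (0.43), with 14, 14, 12, 13, 13 and 14 members higher and 2, 4, 5, 3, 5 and 5 lower (highest adjusted p = 0.0344). When adjusted over the list alone, 4 were lower in COPD and 6 in COPG1, and the other counts were the same. The calls in COPB2, COPG1 and COPZ1 were lost with an estimated correlation (adjusted p = 0.113, 0.11 and 0.0873). In COPE the median was 0.42 with 12 higher and 5 lower (adjusted p = 0.0952), and the list was called there with the RPS16 level (0.36, adjusted p = 0.00911). That level left the COPB1 median at 0.51, still called. PTGS2, the inducible cyclooxygenase, rose by 6.13 ± 0.14 in COPA, 4.33 ± 0.14 in COPB2 and 1.52 ± 0.14 in COPG1. BCL3 in COPG1 (1.71 ± 0.44) and NFKB2 in COPZ1 (1.72 ± 0.32) lost their calls with the RPS16 level (0.4 and 0.36). The 38 genes of the senescence-associated secretory phenotype were called in COPD (median 0.57, 21 higher and 11 lower) and COPZ1 (0.29, 19 and 10), with adjusted p of 0.022 and 0.047. These were 0.0543 and 0.089 with an estimated correlation. The COPZ1 p was 0.0545 without COPZ1 replicate 1 (median 0.33), 0.0513 with the replicate number as a block (0.29) and 0.132 with GC and length offsets (0.33). Higher members numbered 21 and 20 and lower ones 11 and 10 when adjusted over the list alone. The other medians were 0.53 in COPA, 0.15 in COPB1, 0.36 in COPB2, 0 in COPE and 0.27 in COPG1. CXCL8, the interleukin-8 gene, rose from 1.52 ± 0.66 to 155 ± 29.2 CPM in COPA (6.69 ± 0.39), by 4.8 ± 0.36 in COPB1, 4.94 ± 0.36 in COPB2, 5.69 ± 0.37 in COPD and 2.05 ± 0.34 in COPZ1. It was -0.44 ± 0.36 in COPG1, not called, and 1.05 ± 0.34 in COPE, a call lost without Control replicate 3 (adjusted p = 0.0773). IL6 rose by 2.54 ± 0.14 in COPA, 1.71 ± 0.13 in COPB1, 0.56 ± 0.13 in COPB2, 2.15 ± 0.14 in COPD and 0.54 ± 0.13 in COPG1. It was 0.22 ± 0.13 in COPZ1, not called except with GC and length offsets (0.36, adjusted p = 0.0229), and -0.48 ± 0.14 in COPE, called without the RPS16 level but not with it (-0.49, adjusted p = 0.0914).

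Interferon response genes were lower in all 7 knockdowns by the preset test. Of 38 genes, 22 fell in COPA, COPB1 and COPB2, 18 in COPD and COPG1, 17 in COPE and 16 in COPZ1, and 5, 6, 3, 7, 3, 3 and 3 rose in the order COPA to COPZ1. With p adjusted over the list alone, 19 fell in COPD and 2 rose in COPZ1, and the other counts were the same. Medians ran from -0.36 in COPG1 to -1.02 in COPA (highest adjusted p = 0.0286, in COPD). Adjusted p ranged from 0.355 to 0.571 with an estimated correlation, so none of the 7 calls held there. IFIT1 fell in each, from -2.93 ± 0.31 in COPD to -4.54 ± 0.34 in COPB1. The COPD call (median -0.4) was lost without COPD replicate 1 (-0.18, adjusted p = 0.186), COPD replicate 3 (-0.29, 0.0525) or Control replicate 2 (-0.3, 0.0583). It was also lost with the RPS16 level (-0.38, 0.0532), where the median hardly moved. The COPG1 call was lost without COPG1 replicate 2 (-0.29, 0.0556) or Control replicate 2 (-0.34, 0.0507).

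Matrix and contractile genes went in opposite directions between knockdowns. The 40 collagen and matrix genes rose in COPE (median 1.04), COPG1 (1.31) and COPZ1 (0.73), with 32, 32 and 26 higher and 3, 3 and 7 lower (highest adjusted p = 0.000445). These were 33, 32 and 26 higher and 3, 3 and 7 lower when adjusted over the list alone. With an estimated correlation the adjusted p was 0.0641 in COPE and 0.268 in COPZ1, and with the RPS16 level the medians were 0.48, 0.79 and 0.2, still called by the preset test. In COPA the list was called lower (median -0.17, 18 lower and 10 higher, adjusted p = 0.0362), a call lost without COPA replicate 2 (-0.07, adjusted p = 0.102) and with an estimated correlation (adjusted p = 0.514). The RPS16 level took it to -0.57, still called. There 19 were lower when adjusted over the list alone. The median was 0.24 in COPB1, -0.13 in COPB2 and 0.46 in COPD, none called. COL3A1 and COL5A2, fibrillar collagen genes, fell by 3.31 ± 0.1 and by 2.97 ± 0.12 in COPA, while COL11A1 rose by 2.82 ± 0.13 in COPE. COL1A1 stood at 0.15 ± 0.57 in COPA, 0.76 ± 0.57 in COPB2, 2.17 ± 0.59 in COPB1, 2.41 ± 0.6 in COPD, 3.67 ± 0.63 in COPE, 3.93 ± 0.64 in COPG1 and 2.72 ± 0.6 in COPZ1. With the RPS16 level it was called higher in COPG1 (2.09 ± 0.41) and lower in COPA (-1.31), and its values in COPB1 (0.29), COPD (0.55), COPE (1.23) and COPZ1 (0.34) were not called. The matrix proteoglycan gene BGN rose in COPG1 (3.1 ± 0.58), and in COPZ1 (2.83 ± 0.58) it lost its call with that level (0.88).

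The 22 contractile genes of myofibroblasts rose in COPE (median 1.2, 17 higher and 1 lower), COPG1 (0.77, 19 and 0) and COPZ1 (0.62, 17 and 2). They fell in COPA (-1.15, 15 lower and 1 higher), COPB2 (-0.63, 15 and 2) and COPD (-0.43, 12 and 7), with a highest adjusted p of 0.0107. Adjusted over the list alone 20 rose in COPG1, and the other counts were the same. The COPD call was lost with an estimated correlation (adjusted p = 0.188), and the median in COPB1 was -0.15, not called. With the RPS16 level the medians were 0.59 in COPE, 0.38 in COPZ1 and -0.7 in COPD, still called, and COPB1 was called lower (-0.41, adjusted p = 0.00214). The smooth muscle actin gene ACTG2 rose by 2.64 ± 0.23 in COPE, and the tropomyosin gene TPM1 fell by 2.56 ± 0.13 in COPA, by 1.88 ± 0.12 in COPB2 and by 1.6 ± 0.12 in COPD. MYL9 in COPG1 and COPZ1 (3.18 ± 0.76 and 3.47 ± 0.77) and TGFB1 in the same groups (2.25 ± 0.5 and 2.05 ± 0.49) lost their calls with the RPS16 level (0.53, 0.11, 1.07 and 0.47).

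Metabolic groups moved as follows. The 40 nuclear genes of oxidative phosphorylation were lower in all 7 by the preset test, with medians from -0.36 in COPB2 to -0.79 in COPZ1 and 30, 35, 21, 35, 29, 33 and 34 members lower in the order COPA to COPZ1 (highest adjusted p = 0.00298). Numbers adjusted over the list alone were 31, 37, 21, 35, 32, 34 and 35. With an estimated correlation the adjusted p lay between 0.301 and 0.571, so no call held there, and with the RPS16 level the medians were -0.31 in COPA, -0.4 in COPB1, -0.37 in COPD and COPG1, -0.2 in COPE and -0.19 in COPZ1, still called by the preset test. SDHB, a complex II subunit, fell by 1.47 ± 0.18 in COPE and the ATP synthase gene ATP5F1C by 1.39 ± 0.16 in COPB1, while ATP5PB and COX6C in COPZ1 (-1.14 ± 0.2 and -1.1 ± 0.23) lost their calls with that level (-0.37 and -0.18). Cholesterol and fatty acid synthesis genes, 30 in number, rose in COPB1 (median 0.48, 16 higher and 4 lower), COPB2 (0.5, 17 and 5), COPD (0.85, 24 and 3) and COPZ1 (0.6, 22 and 4). Adjusted over the list alone these were 16 and 4, 17 and 6, 25 and 3, and 23 and 4. The adjusted p values were 0.037, 0.00375, 7.66e-07 and 0.000202, and those of COPB1 and COPB2 were 0.225 and 0.0873 with an estimated correlation. The COPB1 call was lost without Control replicate 2 (median 0.46, adjusted p = 0.0507). The desaturase gene SCD rose by 2.23 ± 0.11 in COPB1 and FADS1 by 1.89 ± 0.09 in COPB2, while the fatty acid synthase gene FASN rose in COPD (2.92 ± 0.36) and lost its call in COPZ1 (2.2 ± 0.35) with the RPS16 level (0.92). Medians of this list were 0.49 in COPA, 0.02 in COPE and 0.16 in COPG1, not called, and COPA was called with the RPS16 level (0.37, adjusted p = 0.0239) and with GC and length offsets (0.38, 0.0301).

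Autophagy and lysosome genes, a list of 43, were called higher in COPA (median 0.4, 28 higher and 7 lower), COPB1 (0.29, 22 and 10), COPB2 (0.3, 23 and 6) and COPD (0.27, 22 and 10), with a highest adjusted p of 0.0345. When adjusted over the list alone these were 28 and 8, 22 and 10, 24 and 8, and 22 and 10. With an estimated correlation the adjusted p was 0.0568 in COPA and 0.195 in COPB1 and COPD. Without COPD replicate 3 the COPD value was 0.0617, at an unchanged median of 0.27. MAP1LC3B, an autophagosome marker gene, rose by 3.14 ± 0.33 in COPA and 3.5 ± 0.34 in COPB1. Lipid droplet genes, a list of 16, were called higher in the same 4 (medians 0.73, 0.57, 0.83 and 0.3, with 10, 11, 10 and 10 higher and 4, 4, 3 and 1 lower). Adjusted over the list alone 11 were higher in COPA, COPB1 and COPB2 and 10 in COPD. The adjusted p with an estimated correlation was 0.0543 in COPA and 0.0827 in COPB1. The COPB1 call was lost without COPB1 replicate 1 (median 0.47, adjusted p = 0.0676), Control replicate 2 (0.57, 0.0535) or Control replicate 3 (0.68, 0.0524). GC and length offsets ended the lipid droplet calls in COPA (median 0.73, adjusted p = 0.0679) and COPB1 (0.49, 0.102), with medians equal or close to those above. The RPS16 level took the COPD median to 0.49, still called. G0S2, an inhibitor of triglyceride breakdown, rose by 2.48 ± 0.16 in COPA. Neither list was called in COPE (medians -0.02 and 0.13), COPG1 (0.2 and 0.07) or COPZ1 (0.19 and 0.16), and with the RPS16 level the autophagy list was called in COPG1 (0.27, adjusted p = 0.0401). The 35 Golgi glycosyltransferase genes were called lower in COPA (median -0.42, 21 lower and 7 higher), COPB2 (-0.43, 18 and 6) and COPD (-0.24, 18 and 9), with adjusted p of 0.00973, 0.00957 and 0.0382. In COPA 9 were higher when adjusted over the list alone, and the other counts were the same. The COPD value was 0.0873 with an estimated correlation and 0.0549 without Control replicate 2 (median -0.24). ST3GAL5, a sialyltransferase, fell by 2.23 ± 0.11 in COPA and by 1.61 ± 0.11 in COPB2. Medians in COPB1, COPE, COPG1 and COPZ1 were -0.17, 0.11, 0.17 and -0.08, not called.

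Markers of other cell types were tested as well. Of 6 epithelial markers tested, 4 fell in COPE and 4 in COPG1, the same counts adjusted over the list alone, and the list was called lower there (medians -0.7 and -0.72, adjusted p = 0.0189 and 0.0164). Both calls were lost with an estimated correlation (adjusted p = 0.0715 and 0.0661). The COPE call was lost without any 1 of 5 libraries, COPE replicates 1, 2 or 3 and Control replicates 1 or 2, and the COPG1 call without COPG1 replicate 1 or Control replicates 1 or 2. CLDN4 fell by 1.9 ± 0.22 in COPE and by 2.2 ± 0.23 in COPG1, from 0.91 ± 0.16 CPM in control. Endothelial and leukocyte lists of 8 and 7 tested genes were called in no knockdown (lowest adjusted p = 0.325 and 0.435). The leukocyte medians were 2.55 in COPE, 1.53 in COPG1, 1.78 in COPZ1 and 0 in the other knockdowns. Apart from CD14, the tested leukocyte genes stood at 0 (HLA-DRA) to 0.193 (CD74) CPM in control, without TMM scaling. The highest of them in any library was LAPTM5 at 1.95 CPM, so these medians come from very low counts. The leukocyte gene CD14 was at 1.58 CPM in control, and the endothelial gene TEK, at 122 CPM in control, was the marker with the highest level.

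**Figure D4:**
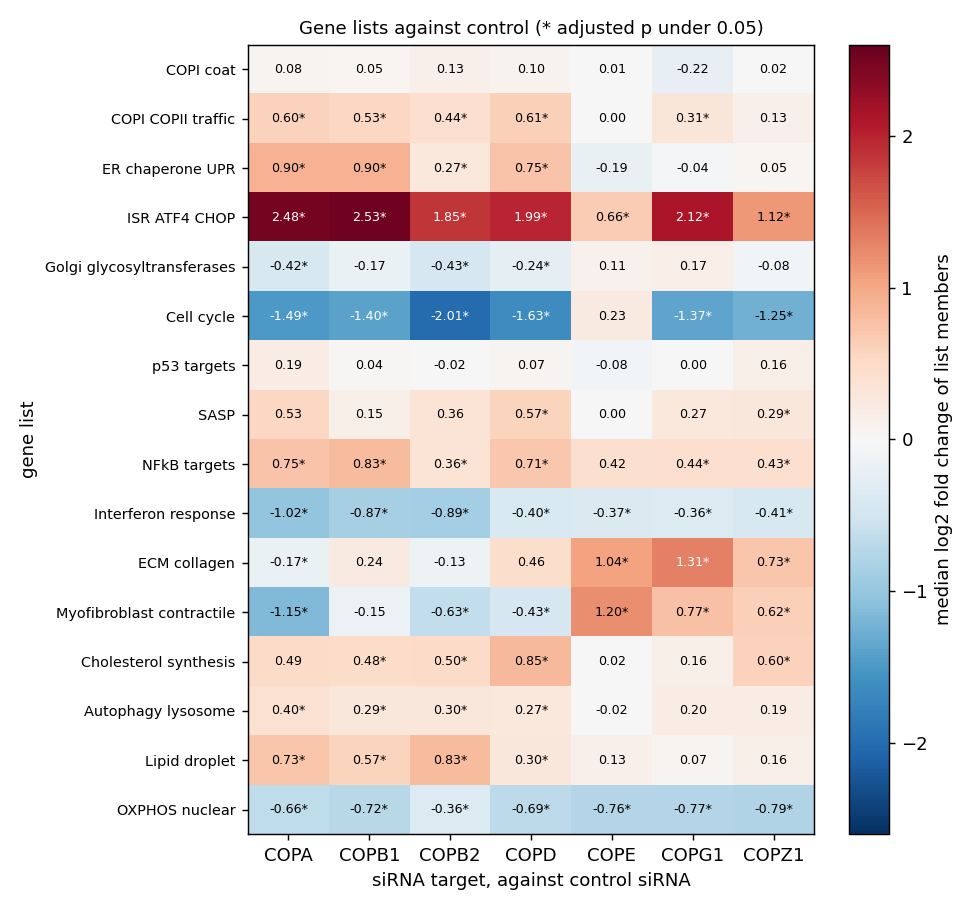
Median log2 fold change of the members of 16 gene lists against control siRNA in each knockdown, as color and number; asterisks mark lists with an adjusted p under 0.05 by the camera test with a preset correlation of 0.01. The stress response row (ISR ATF4 CHOP) runs from 0.66 in COPE to 2.53 in COPB1, and the cell cycle row is at 0.23 in COPE and from -1.25 to -2.01 elsewhere.

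The second question was what the knockdowns shared. PSAT1, the neutral amino acid transporter gene SLC7A5 (2.73 ± 0.32 in COPE to 4.45 ± 0.34 in COPG1), SLC6A9 and the mitochondrial folate enzyme gene ALDH1L2 (2.7 ± 0.35 in COPE to 4.13 ± 0.37 in COPB1) rose in all 7. ADM2, the cytochrome P450 gene CYP1B1 (2.69 ± 0.08 in COPB2 to 3.7 ± 0.08 in COPB1) and SRPRA, a subunit of the signal recognition particle receptor, rose in all 7 as well. BIRC5, RIDA, IFIT1, CCN4, HOPX, the scavenger receptor gene COLEC12, the water and glycerol channel gene AQP3 (-1.52 ± 0.19 in COPZ1 to -4.68 ± 0.23 in COPA) and the glucose transporter gene SLC2A12 (-1.51 ± 0.11 in COPG1 to -3.77 ± 0.13 in COPA) fell in all 7. Each of these 15 genes kept its call in all 7 with the RPS16 level in the model. In all, 1623 genes were higher and 1716 lower in the 7 knockdowns. Independent lists of the same sizes would share 2.5 and 1.8. Simulated unchanged groups with a shared, also simulated, control group shared 0. Groups without changed genes have few calls to share, so this 0 is not the overlap expected for lists of these sizes. With the RPS16 level 734 and 460 were shared, 607 and 388 of which were among the first. Part of the excess may come from the shared controls, which 3 libraries are too few to split.

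Fold changes against control correlated across genes between the knockdowns, with Pearson's r from 0.46 (COPB2 and COPE) to 0.9 (COPA and COPD, COPB1 and COPD) and a median of 0.74 over 21 pairs. Genes are not independent replicates. Unchanged groups simulated with a shared, also simulated, control group gave a mean r of 0.51 and a highest r of 0.55. Covariances ran from 0.56 to 1.6 and the simulated mean was 0.06, a difference of 0.5 to 1.54. The simulation held no property that runs across libraries. In the data the mean RPS16 level was lower in control (-7.15) than in every knockdown group (-5.92 in COPB2 to -1.37 in COPE). How much of the difference in covariance comes from such a property was not tested. COPE correlated more with COPZ1 (0.83) and COPG1 (0.73) than with COPA (0.51), differences that were not tested. These correlations come from the fit without the RPS16 level. COPE (-1.37) and COPZ1 (-1.48) had the highest mean of that level, which may contribute to their likeness and was not tested. The first principal component, with 47.7% of the variance of 2000 genes, placed control, COPE, COPG1 and COPZ1 libraries below 0 (-51.8 to -22.1) and COPA, COPB1, COPB2 and COPD libraries above it (26.1 to 53.9).

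The third question was how the knockdowns differed from each other, tested without the control libraries. Of 21409 genes, 14665 (68.5%) differed among the 7. Against the mean of the other 6, COPE knockdown was set apart by cell cycle genes, of which 47 of 49 were higher and 0 lower (47 and 0 adjusted over the list alone; median 2.08, adjusted p = 8.52e-29). It was also set apart by stress response genes, with 32 of 36 lower and 0 higher (median -1.08, adjusted p = 8.85e-19). Endoplasmic reticulum chaperones (median -0.45, 25 lower and 3 higher), traffic genes (-0.33, 28 and 3), cholesterol synthesis (-0.55, 18 and 4) and autophagy genes (-0.19, 22 and 1) were lower there. Contractile genes (1.12, 18 higher and 1 lower) and matrix genes (0.58, 29 and 3, adjusted p = 0.0854 with an estimated correlation) were higher. TENT5B (3.95 ± 0.14), the long noncoding RNA gene CARMN (3.66 ± 0.1) and the potassium channel gene KCNK2 (3.52 ± 0.1) were highest. BEX2 (-5.46 ± 0.34), INHBE (-4.98 ± 0.14) and RAB39B (-4.4 ± 0.25) were lowest. These values compare knockdowns and are not changes against control. In all 9689 genes differed, 5075 higher and 4614 lower. The secretory list was lower (-0.39, 20 lower and 11 higher), with a call that ended with the RPS16 level (-0.28, adjusted p = 0.0786). Oxidative phosphorylation genes were not called (0.05) but were called higher with that level (0.17, adjusted p = 0.0483).

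COPG1 knockdown differed from the other 6 by higher matrix genes (35 of 40 higher and 2 lower, median 0.93, adjusted p = 3.36e-17), contractile genes (19 of 22 higher, median 0.99) and Golgi glycosyltransferases (18 of 35 higher and 6 lower, median 0.32). Stress response genes were higher too (18 of 36, 7 lower, median 0.37). Endoplasmic reticulum chaperones (-0.23, 17 lower and 1 higher), cholesterol synthesis (-0.27, 14 and 1) and lipid droplet genes (-0.37, 8 and 1) were lower. NF-kB targets were lower at the preset correlation (-0.21, 10 lower and 4 higher) with an adjusted p of 0.0812 at an estimated one. The cell cycle list was also called lower (-0.08, 17 lower and 5 higher). That call was lost without COPG1 replicate 1 (-0.11, adjusted p = 0.0729), with an estimated correlation (0.427) and with GC and length offsets (-0.06, 0.106). Against control the list fell less in COPG1 (median -1.37) than in COPA, COPB1, COPB2 and COPD. The mean of the other 6 includes COPE, where the median against control was 0.23. FGF9, a growth factor gene (4.19 ± 0.12), GRIA4 (4.11 ± 0.11) and WNT2 (3.63 ± 0.13) were highest beside the other 6. CXCL8 (-4.64 ± 0.34), TMEM71 (-4.03 ± 0.24) and LYPLAL1-DT (-3.67 ± 0.25), a divergent transcript, were lowest. CXCL8 was not called against control in COPG1. In all 7500 genes differed, 3840 higher and 3660 lower.

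COPA knockdown differed from the other 6 in 8251 genes, 4215 higher and 4036 lower. BEX2 (3.87 ± 0.15), CXCL8 (3.67 ± 0.18) and RPLP0P2 (3.42 ± 0.11) were higher, and CARMN (-4.09 ± 0.18) and WNT2 (-3.6 ± 0.26) lower. Contractile genes (18 of 22 lower and 0 higher, median -1.14, adjusted p = 2.41e-16) and matrix genes (34 of 40 lower and 1 higher, -0.76, adjusted p = 4.04e-16) were lower, as were glycosyltransferases (-0.17, 16 of 35 lower; -0.09 with the RPS16 level, still called). Stress response (0.67, 26 of 36 higher), chaperone (0.3, 24 of 35), traffic (0.22, 23 of 48), NF-kB (0.32, 13 of 22) and autophagy genes (0.2, 21 of 43) were higher. The cell cycle list was lower (-0.52, 32 of 49 lower) with an adjusted p of 0.0854 with an estimated correlation. Interferon genes were not called (-0.38, adjusted p = 0.061) but were called lower with the RPS16 level (0.0479), with the mitochondrial rRNA level (0.0458) and without COPA replicate 3 (0.012).

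COPB1 knockdown differed in 6222 genes, 3263 higher and 2959 lower, with INHBE (2.56 ± 0.08), the kinase gene MAP2K6 (2.49 ± 0.09) and ANKRD1 (1.99 ± 0.1) highest and TMEM35A (-2.28 ± 0.14) and the Wnt antagonist gene DKK2 (-2.21 ± 0.19) lowest beside the target. Stress response (0.58, 28 of 36 higher), chaperone (0.53, 24 of 35) and traffic genes (0.16, 23 of 48) were higher. Contractile genes were lower (-0.39, 12 of 22), with an adjusted p of 0.0585 with an estimated correlation. Matrix, cell cycle and NF-kB calls were each lost without 1 library: matrix (-0.11) without COPB1 replicate 1 (adjusted p = 0.0873), cell cycle (-0.19) without COPB1 replicate 2 (0.0553) and NF-kB (0.1) without COPB1 replicate 2 (0.0651). With an estimated correlation these were at 0.427, 0.39 and 0.0965. Targets of p53 (-0.18, adjusted p = 0.0375) and oxidative phosphorylation genes (-0.11, 0.026) were called lower with the RPS16 level, the latter also with GC and length offsets (-0.12, 0.0396).

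COPB2 knockdown differed in 10209 genes, 5388 higher and 4821 lower, and in 5078 with the RPS16 level in the model. HMOX1, the inducible heme oxygenase, was higher by 3.22 ± 0.05 (573 ± 36.2 CPM against 69.2 ± 35.4 in the other 18 libraries, adjusted p = 6.66e-22), as were HTRA3 (2.47 ± 0.07) and the fatty acid binding protein gene FABP3 (2.41 ± 0.1). ADAM19 (-3.04 ± 0.24) and the claudin gene CLDN11 (-2.8 ± 0.08) were lower. Cell cycle (-0.97, 39 of 49 lower and 4 higher), contractile (-0.87, 20 of 22 lower) and matrix genes (-0.66, 32 of 40 lower) were lower, and lipid droplet genes higher (0.33, 9 of 16). Oxidative phosphorylation genes were higher (0.45, 24 of 40), a call lost with an estimated correlation (adjusted p = 0.522) and with the RPS16 level (0.1, adjusted p = 0.322). Autophagy genes (0.16, 21 of 43) had an adjusted p of 0.105 with an estimated correlation. The matrix median was -0.39 and the lipid droplet median 0.18 with the RPS16 level, still called. Stress response (0.14), interferon (-0.29) and glycosyltransferase genes (-0.14) were not called but were with that level (adjusted p = 0.00187, 0.0479 and 0.0479) and with the mitochondrial rRNA level (0.00296, 0.0096 and 0.0458). The stress response call also appeared without COPB2 replicate 1 (0.0164) or 2 (0.0143).

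COPD knockdown differed in 3647 genes, 2059 higher and 1588 lower, and in 2265 without COPD replicate 2. The interferon list was not called (0.21, adjusted p = 0.114), and it was called higher without COPD replicate 1 (0.37, adjusted p = 4.98e-05). Cholesterol synthesis genes were higher (25 of 30 and 0 lower, median 0.58, adjusted p = 6.66e-20), with 27 adjusted over the list alone. Chaperone (0.4, 22 of 35), secretory (0.15, 17 of 38), traffic (0.19, 16 of 48), stress response (0.15, 12 of 36), lipid droplet (0.28, 7 of 16) and epithelial marker genes (0.56, 4 of 6) were higher, and contractile genes lower (-0.38, 12 of 22). The retinoic acid binding protein gene CRABP2 (2.08 ± 0.08) and the keratin gene KRT19 (2.07 ± 0.09) were among the highest, and TAF9B (-2.2 ± 0.1) and NDUFAF8 (-1.95 ± 0.14) lowest. Cell cycle genes (-0.24, 13 of 49 lower) had an adjusted p of 0.0881 with an estimated correlation, and the oxidative phosphorylation call (-0.08) was lost without COPD replicate 1 (adjusted p = 0.687) and with an estimated correlation (0.643).

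COPZ1 knockdown differed in 7556 genes, 4021 higher and 3535 lower. Stress response (-0.59, 26 of 36 lower and 0 higher), chaperone (-0.36, 18 of 35), traffic (-0.27, 25 of 48) and lipid droplet genes (-0.28, 8 of 16) were lower, and contractile genes higher (0.79, 16 of 22). Matrix genes were higher (0.34, 19 of 40) and autophagy genes lower (-0.11, 15 of 43), with adjusted p of 0.235 and 0.169 with an estimated correlation. These medians were 0.17 and -0.05 with the RPS16 level, still called by the preset test, and oxidative phosphorylation genes were called higher (0.12, adjusted p = 0.0484). GC and length offsets ended the autophagy call (adjusted p = 0.0585) at a median of -0.12. RIPOR2 (2.19 ± 0.11), the integrin gene ITGA7 (1.75 ± 0.12) and DENND2A (1.74 ± 0.09) were highest, and NCEH1, a cholesteryl ester hydrolase gene (-1.97 ± 0.07), and UTP14A (-1.54 ± 0.09), a ribosome biogenesis gene, lowest. The coat list against the other 6 is left unread, because each of those groups has a coat gene of its own lowered by siRNA.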

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

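The tests of the RPS16 level, of GC content and length, of the control libraries in the interferon result and of the cell cycle result in COPE were chosen after the results had been seen. Of the lists called in the direct test against the other 6 knockdowns, those of matrix, contractile and cell cycle genes bear on the patterns below. Matrix genes had medians of -0.76 in COPA, -0.11 in COPB1, -0.66 in COPB2, 0.58 in COPE, 0.93 in COPG1 and 0.34 in COPZ1. With an estimated correlation the adjusted p was 0.427 in COPB1, 0.0477 in COPB2, 0.0854 in COPE and 0.235 in COPZ1. Contractile genes had medians of -1.14 in COPA, -0.39 in COPB1 (adjusted p = 0.0585 with an estimated correlation), -0.87 in COPB2, -0.38 in COPD, 1.12 in COPE, 0.99 in COPG1 and 0.79 in COPZ1. Cell cycle genes had a median of 2.08 in COPE, and the list was called lower in 5 of the other knockdowns by the same test. In those 5 tests the mean of the other 6 includes COPE, where the list did not fall against control. With an estimated correlation only the COPB2 call held (adjusted p = 0.00859, against 0.0854 in COPA, 0.39 in COPB1, 0.0881 in COPD and 0.427 in COPG1).

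The first pattern weighed was the 10929 genes called against control in COPE and the 11308 in COPZ1. With the RPS16 level as a covariate 3811 and 3809 were called. Among lost genes the median size of change went from 0.73 to 0.24 in COPE (SE 0.17 to 0.2) and from 0.74 to 0.26 in COPZ1 (SE 0.17 to 0.2). The calls thus ended mainly because the fitted changes shrank. The control libraries lay at -7.47 to -6.6 of the level and the COPE and COPZ1 libraries at -2.16 to -1, without overlap. The shrinkage therefore rests on the model's assumption that each gene has the same straight slope on the level in all groups. In counts simulated with this level and 200 changed genes in each, the model without it made 5015 false calls in COPE and 4527 in COPZ1, and the model with it 5 and 2. The level was built into these counts with slopes fitted on the real data, so the advantage of the model with it was fixed in advance. The false calls show what such a level can produce, not that the real calls are false. The model with the level recovered 108 of the 200 changed genes in each, so some of the lost calls may be real changes that it missed. The level was then shuffled within groups 40 times, and 5 of 41 assignments in COPE and 3 of 41 in COPZ1, the real one included, called as few genes (shuffles 3388 to 9401 and 3470 to 9732). GC and length offsets left 10988 genes called in COPE, which argues against that explanation.

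The bound for this shuffle test had been set before its result: at least 1 in 20 assignments with as few calls was to count against a library property, and 5 of 41 and 3 of 41 met it. It was judged wrong after the result was seen, and the question is left open here instead. As a share, these are 12.2% in COPE (95% binomial interval 4.08% to 26.2%) and 7.32% in COPZ1 (1.54% to 19.9%), intervals computed after the result. They count the real assignment as a draw, so they are not sampling intervals of the shuffles and do not decide whether a share lies above 1 in 20. Shuffling within groups keeps the group means of the level, so each shuffled level still overlaps with the group difference. All 40 shuffles in each knockdown called fewer genes than the model without the level (at most 9401 against 10929 in COPE and 9732 against 11308 in COPZ1). A low count can therefore come from this overlap, and the number of calls does not separate the explanations. The real level called fewer genes than 36 of 40 shuffles in COPE and 38 of 40 in COPZ1, and 7455 genes followed it within groups against 0 in each shuffle, the direction a library property predicts. A reader who keeps the first bound would hold the library property excluded as the cause of the lower counts. The level differs between groups, so a library property and an effect of the knockdowns on RPS16 cannot be told apart, and the biological explanation was not tested separately.

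The second pattern was the lower interferon list in all 7 knockdowns. Without 1 control library, 19 of 21 tests still called it lower. The 2 others were COPD (median -0.3, adjusted p = 0.0583) and COPG1 (-0.34, 0.0507) without Control replicate 2. Their medians with all libraries were -0.4 and -0.36. Under the bound set for this test, a call lost in at least 1 of 7 knockdowns was what 1 control library would give. That bound was met, so the explanation is not excluded. With the RPS16 level 6 of 7 knockdowns kept the call, which argues against that level as the whole cause. With an estimated correlation none of the 7 calls held (adjusted p 0.355 to 0.571), so the pattern rests on the preset test. IFIT1 stood at 72.3 CPM in the controls, and a response of these cells to their own transfection may have raised the reference, which no untransfected libraries were analysed to test.

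The third pattern was the cell cycle list in COPE, higher than in the other 6 knockdowns. Against control it was not called in COPE (median 0.23, adjusted p = 0.0661), while in the other 6 the medians were -1.25 to -2.01, so the difference is mainly a fall that COPE did not show. A weaker knockdown of the mRNA is argued against by the 4.66% of target mRNA left, and the RPS16 level by a median of 2.05 against the other 6 with it in the model. Why COPE lacked the fall was not tested, nor were cell numbers or siRNA off-target effects.

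Other splits of the libraries were counted for each number of changed genes. Each comparison with control has 10 splits of 6 libraries, too few for a share under 0.05. The real split gave the most calls (1 of 10) in COPA (12195, highest other 0), COPB1 (12673, 0), COPB2 (10262, 0), COPD (11710, 0), COPE (10929, 2), COPG1 (11404, 1) and COPZ1 (11308, 1). Against the other 6 knockdowns 1 of 60 splits, the real one, gave as many calls: COPA 8251 (highest other 6077), COPB1 6222 (1148), COPB2 10209 (2590), COPD 3647 (1588), COPE 9689 (4881), COPG1 7500 (754) and COPZ1 7556 (1828). The joint test gave 14665 genes, 1 of 60 splits, with a highest other of 3499. A share of 1 in 60 is the smallest these splits can give. They redrew all knockdown groups at once, so drawn groups mixed different knockdowns. The splits therefore ask only whether the knockdown libraries are interchangeable, and they do not exclude chance for a single knockdown.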

How the results depend on the processing

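The covariates, GC and length offsets, protein-coding genes alone and the library left out for its mitochondrial rRNA were chosen after the data had been seen. Counts of called genes stayed within 1.5 times under DESeq2, its size factors, both low-count filters, the replicate block, fits of 1 knockdown with control, GC and length offsets, protein-coding genes alone and the mitochondrial rRNA covariate. With the RPS16 covariate they moved to 3811 in COPE, 6677 in COPG1 and 3809 in COPZ1 against control, 5078 in COPB2 against the other 6, and 1194 shared by all 7; why the level differs between libraries was not tested. An absolute log2 fold change of at least 1, a stricter call by construction, gave 6143, 6149, 4468, 5209, 3900, 4436 and 4094 against control (COPA to COPZ1), 1856, 846, 2003, 477, 2706, 1731 and 1186 against the other 6, and 686 shared. Leaving out 1 library moved COPD against the other 6 to between 2265 (without COPD replicate 2) and 3114, with fewer samples tested. The RPS16 covariate turned the sign of ARCN1 (-0.03), COPB1 (0) and DDIT3 (0.17) in COPE, of COL1A1 (-1.31) and COPE (0.24) in COPA, of COPG2 in COPE (-0.29), COPG1 (-0.02) and COPZ1 (-0.28), and of MKI67 in COPZ1 (-0.9). GC and length offsets turned COPA in COPZ1 (-0.01) and COPG1 in COPE (-0.17), and the fry test turned the coat list in COPG1 against the other 6 (median 0.59, adjusted p = 0.00797), a test left unread; the cause was not tested. Of 471 values of named genes, 395 kept direction and side of the threshold with the RPS16 covariate, 56 lost their call and 11 gained one; of the 9 that turned sign, 6 lost their call and 3 gained one. DESeq2 kept all 471. Of 266 list tests, 50 lost their call with an estimated correlation and 3 with the RPS16 covariate, with which 17 gained one. The fry test, which compares a list with no change and not with other genes, ended 3 calls and started 81. The mitochondrial rRNA covariate ended 3 list calls (against the other 6, cell cycle in COPB1 and COPG1 and oxidative phosphorylation in COPB2) and started 8. Leaving out the library of each knockdown with the highest level started 6 and ended 10: against control the secretory list in COPD and COPZ1, lipid droplets in COPA and COPB1, matrix in COPA and interferon in COPD, and against the other 6 autophagy and lipid droplets in COPB2, oxidative phosphorylation in COPD and the secretory list in COPE. The stricter filter left too few endothelial and leukocyte genes to test; of the other tests 224 were the same and 14 lost their call. These were, against control, matrix in COPA, glycosyltransferases in COPD, interferon in COPG1, lipid droplets in COPB1 and epithelial markers in COPE, and against the other 6, autophagy in COPZ1, the coat in COPB2, cell cycle in COPB1 and COPG1, matrix and NF-kB in COPB1, lipid droplets in COPB2 and COPZ1, and oxidative phosphorylation in COPD. Protein-coding genes alone started 1 call and ended 10: against control matrix in COPA, glycosyltransferases in COPD, interferon in COPD and COPG1 and the secretory list in COPZ1, and against the other 6 cell cycle in COPB1 and COPG1, matrix in COPB1, lipid droplets in COPB2 and oxidative phosphorylation in COPD. No low-count filter started 22 and ended 2, the epithelial list in COPE and COPG1. Leaving out 1 library ended 26 calls, all named in the report, and started 13. Replicate numbers share a label only: 84 pairs with the same number had a median correlation of 0.01 (-0.407 to 0.456), and 5 of 24 libraries correlated best with their own number. The block ended the calls of COPB2 in COPG1 (-0.22, adjusted p = 0.056), MT-ATP8 in COPE (0.0718), RNA5-8SN1 and RNA5-8SN3 in COPG1 (0.0516 and 0.0505), RNA5-8SN2 and RNA5-8SN3 in COPB1 (0.0572 and 0.061) and the secretory list in COPZ1 (0.0513), and no other.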
